A study of Arabidopsis thaliana with 3 samples.

How the data were processed

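Transcript levels were compared between SCR:PIF1/pifQ and pifQ etiolated seedlings of Arabidopsis thaliana on 3 two-colour Agilent arrays. pifQ lacks the 4 transcription factors PIF1, PIF3, PIF4 and PIF5, and in SCR:PIF1/pifQ the promoter of SCR, an endodermis gene, drives PIF1. Each array held 1 SCR:PIF1/pifQ sample in red (Cy5) and 1 pifQ sample in green (Cy3), with the same dye orientation on all 3 arrays, so no dye swap was available. The labels call the arrays biological replicates. Per the labels' protocols, seeds were kept at 4 °C for 3 days, lit with white light of 60 µmol per square metre and second for 6 hours and held in the dark for 2.5 days, and 25 ng of total RNA was labelled. The tissue label reads etiolated seedlings, whereas the extraction protocol names seeds as the source of the RNA. Both are stated here because seed transcripts enter the results.

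The deposited scanner files hold spot intensity values that the authors obtained with Agilent Feature Extraction 9.5.1.1, per the file headers. Mean signals were deposited to 3 significant digits. Per the file headers, the software also gave processed intensity values, background-subtracted and dye-normalized with an intensity-dependent fit, and their log10 ratio of red over green. The authors' deposited value table holds log2 ratios of red over green, and the submitters' processing notes name limma, whose version was not given in the sources used here. Setting the table against the scanner files showed that its values are median signals corrected by normexp with an offset of 50 and normalized by loess within each array. No scale, centring or direction of the table stayed unknown. Its column medians were -4.96e-06, 0.00369 and 0.00291 for replicates 1, 2 and 3.

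From the files, mean signals were background-corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3 and normalized by loess within each array, with control spots at weight 0. Spots flagged as outliers were left out (82, 41 and 33 on the 3 arrays), spots of a probe were averaged, and no spot was saturated. A probe was kept when it was well above background in at least 1 channel on at least 2 of the 3 arrays. Of 43603 probes, 37029 (84.9%) were matched to 1 locus through accessions, locus tags or symbols of the TAIR10.1 reference table, which was used for names and gene order alone. The brightest kept probe gave the value of a gene, and 22407 genes were tested. Of 129 named genes, 60 had other kept probes, and in 7 of these another probe had the opposite sign: PIF1, GAPC1, LTP1 and XTH4 past the threshold, and LHCB4.1, PDF1 and UBQ10 short of it. The files place probes on build ath1:Jan2004.

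The log2 ratio of SCR:PIF1/pifQ over pifQ was tested against 0 with limma (lmFit and eBayes, two-sided, Benjamini-Hochberg adjusted p under 0.05). Errors are SDs over the 3 arrays. All 3 arrays lay on 1 slide and came from 1 scan, so slide and scan could not be fitted as a block. The number of arrays limits the precision. Between 34213 and 35264 probes were well above background in green and between 34232 and 34986 in red. Spike-in transcripts gave observed over expected log ratios with slopes of 0.884, 0.888 and 0.886, per the file headers, so ratios in these fits were somewhat compressed. The intercepts of these fits were 0.44, 0.17 and 0.43 on the log2 scale, per the file headers, so the fitted ratio of a spike-in expected at 0 lay above 0 on all 3 arrays. The fits are those of Feature Extraction, and spike-ins were not fitted in the loess ratios used here. Whether the compression and the offset remain in the loess ratios was therefore not tested. The intercepts are of the size of the median absolute log2 ratio of the genes past the threshold, 0.31. In 56 genes pifQ, and in 131 genes SCR:PIF1/pifQ, was not well above background on any array, and none of these is named here.

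Gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The named genes were the members of the PIF quartet and SCR, the 10 largest rises and 10 largest falls among genes past the threshold with a symbol, 1 sign on all 3 arrays and both channels well above background, and up to 4 members of each list with the smallest adjusted p. Of 30 lists, 28 were tested with camera (preset inter-gene correlation 0.01), camera with an estimated correlation, and fry, with adjustment over lists. The plastid-encoded and mitochondrion-encoded lists found no locus in the table. In the 28 tested lists, 8 members went unmatched, 7 of them photosystem subunits whose symbols the reference writes with a hyphen.

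On simulated data for this comparison, with 22407 genes of which 200 were changed, the fit recovered 60.0% of the genes changed by 0.25 on the log2 scale and 100% of those changed by 0.5, 1 or 2. It called 31 unchanged genes, beside 30 of 50 changed by 0.25 and 50 of 50 at each larger size. The share of false calls was thus above the 0.05 of the threshold. In the data 12734 genes passed, so neither this share nor the recovery carries over to them. Camera with the preset correlation called the 1 list that had been moved and no other, and camera with an estimated correlation called 0 lists there. The simulated genes were drawn independently of each other, whereas estimated correlations in the data reached 0.47 (root hairs). The simulation therefore cannot show how often the preset correlation calls unmoved lists of correlated genes.

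Alternatives covered background correction, within-array and between-array normalization, the filter on dim probes, the probe rule, the variance model, pairing by array, a 2-fold threshold, the deposited value table and each replicate left out. Removal of a probe GC trend and the addition of the hyphenated photosystem members were chosen after seeing the data.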

Results

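The data comprised 3 two-colour arrays, each setting 1 SCR:PIF1/pifQ sample against 1 pifQ sample of dark-grown seedlings. PIFs are bHLH transcription factors that repress light responses in the dark, and the quadruple mutant pifQ lacks 4 of them. The comparison asks which transcripts differ when PIF1 is returned under the endodermal SCR promoter. Median mean signals were 1490, 1100 and 1120 in green and 2280, 2340 and 2090 in red, against median backgrounds of 42.5 to 45.0 and 51.5 to 52.0. The ratios of arrays 1 and 2, 1 and 3, and 2 and 3 correlated across genes at 0.928, 0.895 and 0.937, where genes are not independent replicates.

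The 2 probes for PIF1 (AT2G20180) went in opposite directions. The probe at chromosome 2, 8712535 to 8712594 (build ath1:Jan2004), nearer the 5' end of the transcript, was higher in SCR:PIF1/pifQ, with a log2 ratio of 1.09 ± 0.26 (SD, n = 3, limma adjusted p = 2.81e-04). The brighter probe at 8711135 to 8711194, nearer the 3' end, was lower, at -0.49 ± 0.09 (SD, n = 3, limma adjusted p = 7.02e-04). Each direction held on all 3 arrays. The probes of PIF1, PIF3, PIF4 and PIF5 were well above background in pifQ on all 3 arrays, where the brightest probes had mean log2 signals of 11.9, 13.4, 6.85 and 8.14. The parts of these transcripts that the mutations and the transgene leave are not given in the sources used here, so the probes do not settle whether the labels hold. The mean over probes gave PIF1 0.30, against -0.49 by the brightest probe. SCR was higher by 0.34 ± 0.08 by its brightest probe, and its other probe was at 0.18 ± 0.21 and did not pass. PIF5 was lower, at -0.29 ± 0.12, and at -0.53 with Agilent's processed signals. PIF3 (0.032 ± 0.05) and PIF4 (-0.064 ± 0.0043) did not pass after loess, and after median centring they stood past the threshold at 0.28 and -0.44.

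**Figure D1:**
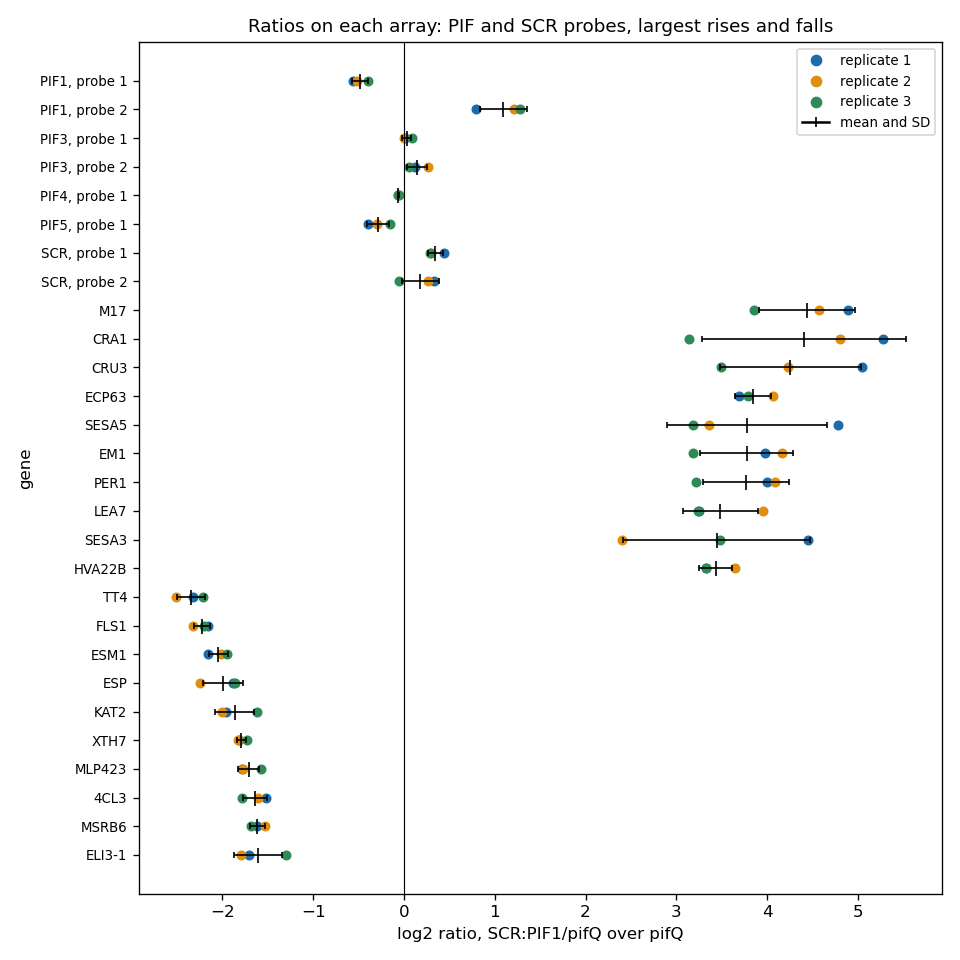
Log2 ratio of SCR:PIF1/pifQ over pifQ on each of the 3 arrays (coloured points), with mean and SD (black), for the probes of the PIF genes and SCR and for the 10 largest rises and falls named by rule. Probe 1 is the brightest of a gene; the PIF1 probes lie at -0.49 and 1.09, and the rises range from 3.44 to 4.44.

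The largest named rises included CRA1, CRU3, SESA5, EM1, PER1 and SESA3 of the seed storage and late embryogenesis list. The others, M17, ECP63, LEA7 and HVA22B, were in no tested list. M17 (AT2G41260), a late embryogenesis gene, was higher by 4.44 ± 0.53 on the log2 scale (SD, n = 3), and the cruciferin storage proteins CRA1 and CRU3 were higher by 4.40 ± 1.12 and 4.26 ± 0.78 by their brightest probes. The other probe of CRU3 was higher by 1.59 ± 0.38, so the size of that rise depends on the probe. The list of seed storage and late embryogenesis genes had 19 of 20 measured members higher and 0 lower, with a median log2 ratio of 2.71. The list median varied between replicates, at 3.54, 1.95 and 2.46 on arrays 1, 2 and 3. EM6, EM1, PER1 and the oleosin OLEO2 rose by 3.32 ± 0.36, 3.77 ± 0.52, 3.77 ± 0.47 and 3.43 ± 0.51. ECP63, SESA5, LEA7, SESA3 and HVA22B completed the 10 largest rises, at 3.44 to 3.85. The list shifted upward by camera (limma, adjusted p = 4.72e-09), a call lost with an estimated correlation (adjusted p = 0.424). No tested list passed in that setting, so it does not tell shifted lists from others. The extraction protocol names seeds as the RNA source, while the tissue label reads etiolated seedlings.

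Genes known to be bound by or to depend on PIFs were mostly higher. Of 20 measured members, 15 rose and 2 fell, with a median of 0.45. PIL1, a PIF-like bHLH gene induced in shade, rose by 2.83 ± 0.16, the wall enzyme gene XTH15 by 2.19 ± 0.29 and ST2A by 1.79 ± 0.03 (SD, n = 3), and SOM, a repressor of seed germination, was 2.29-fold higher. Camera gave an adjusted p of 2.81e-05 (limma), and the adjusted p was 0.424 with an estimated correlation. After median centring the median was 0.77 (adjusted p = 0.00398 in limma).

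Nuclear genes of the photosynthetic apparatus were lower after loess, but the medians of all 4 lists turned when arrays were only median-centred. Of 21 antenna genes 15 fell and 0 rose (median -0.36), led by LHCB1.4 (-1.42 ± 0.14) and LHCB3 (-1.13 ± 0.16), yet after median centring 14 were higher and 2 lower, with a median of 0.50. Other probes lay between -1.95 and -0.49 for LHCB1.4, and the other probe of PSBO2 was at -0.79. Of 19 photosystem subunits 16 fell and 1 rose (median -0.66, against 0.39 after median centring), among them PSAH2 (-1.39 ± 0.13) and PSBO2 (-1.20 ± 0.06). Of 14 genes of electron transport and ATP synthase 11 fell and 0 rose (median -0.45, against 0.31), with FNR2 at -1.14 ± 0.04 and ATPD at -1.06 ± 0.05. The Calvin cycle list had 13 members lower and 4 higher of 20 (median -0.46, against 0.47), with GAPA-2 at -1.01 ± 0.09 and the Rubisco small subunit gene RBCS2B at 1.03 ± 0.19. The other Rubisco small subunit genes of the list went both ways after loess: RBCS1B at -1.19 ± 0.31, RBCS3B at 0.93 ± 0.29 and RBCS1A at 0.31 ± 0.14. LHCB1.4 was at 0.045 after median centring and did not pass, nor did ATPD (-0.11) and GAPA-2 (-0.035), while LHCB3, LHCB4.1, PSAK and EMB3119 were past the threshold as higher, at 0.20, 0.37, 0.43 and 0.25. With Agilent's processed signals LHCB1.4 was at -0.85 and RBCS2B at 0.45, and LHCB4.1 did not pass, at -0.21. The Calvin cycle list had a camera adjusted p of 0.0306 after median centring (limma), and the other 3 lists did not pass there.

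Chlorophyll genes were mostly lower after loess with the same turn, and the carotenoid list kept a median below 0 with fewer members lower. Of 28 genes of tetrapyrrole and chlorophyll synthesis 24 fell and 3 rose (median -0.56, against 0.096 after median centring), with CAO, which makes chlorophyll b, at -1.31 ± 0.09 and the magnesium chelatase subunit gene CHLH at -1.29 ± 0.19. The 3 that rose were PORA (0.83 ± 0.27), PORB (0.79 ± 0.22) and FC1 (0.18 ± 0.07), while PORC fell (-0.75 ± 0.11). Of 16 carotenoid genes 13 fell and 1 rose (median -0.45), against 6 lower and 3 higher after median centring (median -0.064), led by PSY, the phytoene synthase gene, at -1.12 ± 0.10. Among 17 regulators of chloroplast development 9 fell and 2 rose (median -0.23, against 0.13), with HYH at -0.67 ± 0.08, SIG2 at -0.71 ± 0.15 and GNC at -0.53 ± 0.04 by their brightest probes, where other probes of HYH and GNC were at -0.27 and -0.34. Camera adjusted p values for these 7 lists ran from 1.20e-06 to 0.0455 (limma), and with an estimated correlation the adjusted p was 0.424 for 6 of them and 0.545 for the Calvin cycle. Without replicate 1 the Calvin cycle list (adjusted p = 0.0651), and without replicates 2 or 3 the list of regulators (adjusted p = 0.0509 and 0.0901), did not pass camera in limma. The list of regulators also did not pass with Agilent's processed signals or with the mean over probes.

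The dye ratio rose with brightness before loess. After median centring the brightest 2241 genes had a median log2 ratio of 0.70 and the dimmest 2241 a median of -0.29, and 17 of the 21 antenna genes and 18 of the 19 photosystem genes were among the brightest 2241. Set against genes of like brightness, the median-centred antenna and photosystem lists were at -0.19 and -0.63, a comparison chosen after seeing the data that removes the brightness trend much as loess does. Without a dye swap the arrays do not settle which part of that trend belonged to the dyes.

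**Figure D2:**
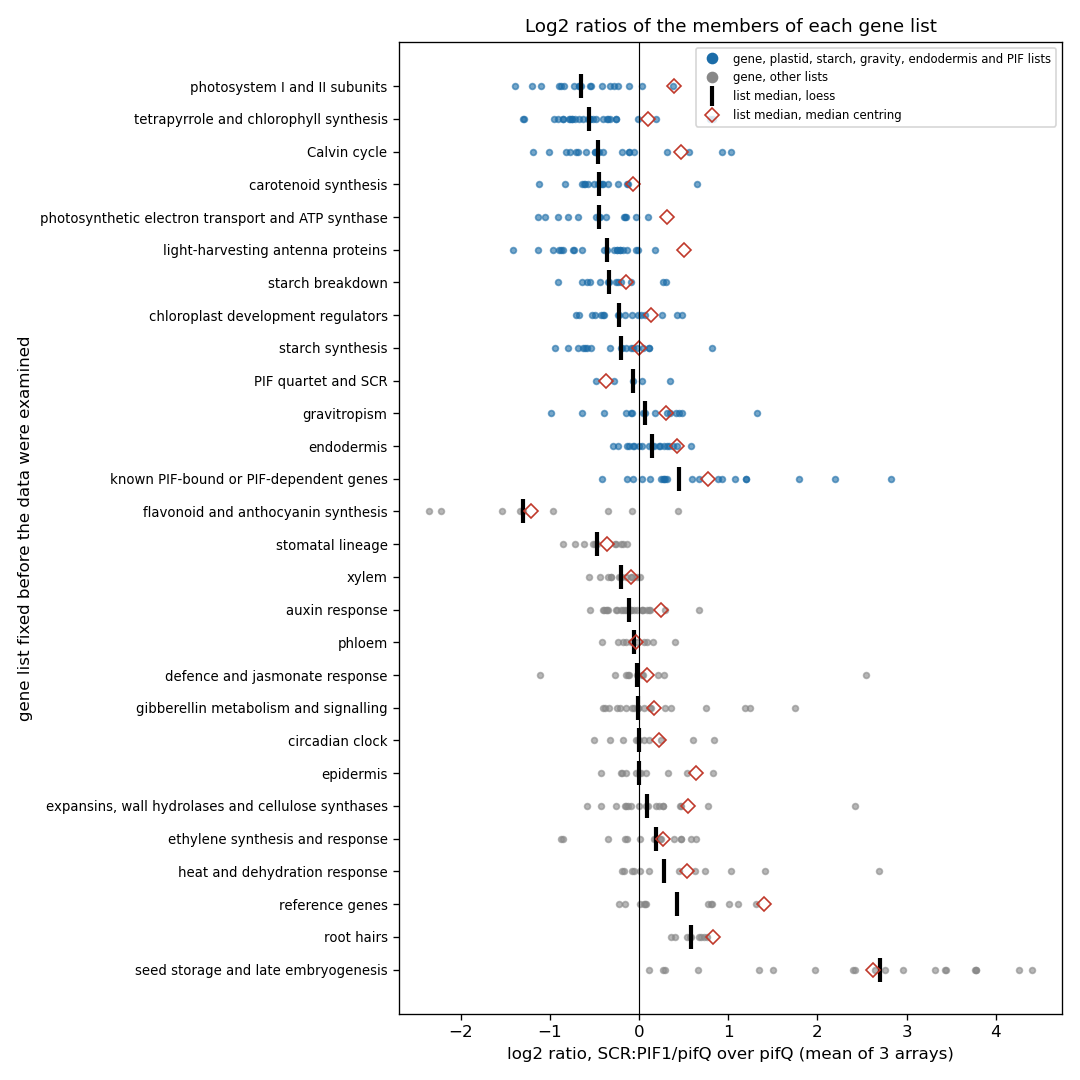
Log2 ratio (mean of 3 arrays) of every measured member of the 28 gene lists, with the list median after loess (black bar) and after median centring (red diamond). The antenna list has medians of -0.36 after loess and 0.50 after median centring, and the seed list 2.71 and 2.63; 10 of the 28 medians change sign.

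Starch genes were lower by small amounts after loess. Of 18 genes of starch synthesis 11 fell and 1 rose (median -0.20, against 0.0017 after median centring), with the ADP-glucose pyrophosphorylase genes APL1 and APL4 at -0.94 ± 0.13 and -0.80 ± 0.04 and the glucose phosphate transporter gene GPT2 higher, at 0.82 ± 0.06 (adjusted p = 0.0590 with no replicate block in limma). Of 13 genes of starch breakdown 9 fell and 2 rose (median -0.34, and -0.15 after median centring), with the phosphorylase gene PHS1 at -0.91 ± 0.20 and DPE1 at -0.64 ± 0.08 by its brightest probe and -0.29 ± 0.18 by another. Both lists had a camera adjusted p of 0.0144 (limma), and the adjusted p was 0.513 with an estimated correlation.

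Neither the gravitropism nor the endodermis list passed camera. Of 15 gravitropism genes 7 rose and 3 fell, among them LZY3 (1.32 ± 0.14, and 2.38 with Agilent's processed signals) and the auxin efflux carriers PIN7 (-0.99 ± 0.08) and PIN3 (-0.64 ± 0.09, and -0.077 without passing after median centring). The gravitropism list had a median of 0.061, and 0.30 after median centring (camera adjusted p = 0.390 after loess, limma). Of 19 endodermis genes 9 rose and 1 fell (median 0.15, and 0.43 after median centring; camera adjusted p = 0.102 after loess, limma), with the Casparian strip genes CASP5 and CASP4 at 0.58 ± 0.24 and 0.42 ± 0.10 and SCL3 at 0.38 ± 0.02 by its brightest probe, while its other probe (0.080 ± 0.17) did not pass.

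Flavonoid genes held the largest named falls. Of 9 measured genes 7 fell and 1 rose (median -1.30, and -0.35 without a filter on dim probes), led by the chalcone synthase gene TT4 (-2.35 ± 0.15) and the flavonol synthase gene FLS1 (-2.23 ± 0.09). The other largest named falls, a ranking that left out genes without a symbol, were ESM1 (-2.05 ± 0.11) and ESP (3.99-fold lower), both of glucosinolate breakdown, the potassium channel gene KAT2 (-1.87 ± 0.21), XTH7, MLP423, 4CL3, MSRB6 and ELI3-1, the last 5 between -1.79 and -1.61 by their brightest probes. Other probes of 4CL3 and ELI3-1 were at -0.55 and -1.06, and those of MLP423 between -1.56 and -1.31, so their place among the largest falls depends on the probe. Flavonoid genes shifted downward by camera (limma, adjusted p = 4.50e-04), and the adjusted p was 0.424 with an estimated correlation.

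Of 5 lists of markers of other cell types, those of root hairs, stomatal lineage and xylem passed camera, and those of epidermis and phloem did not (adjusted p = 0.879 and 0.679, limma). All 9 root hair genes rose (median 0.59), with RSL4 at 0.72 ± 0.14 and LRX1 at 0.76 ± 0.18. Of 11 stomatal lineage genes 10 fell and 0 rose (median -0.48), with KAT1 at -0.85 ± 0.11 and EPF2 at -0.61 ± 0.08, and of 13 xylem genes 8 fell and 0 rose (median -0.20, and -0.087 after median centring). Camera adjusted p values were 1.99e-04, 1.84e-04 and 0.0144 (limma), and with an estimated correlation the adjusted p was 0.424, 0.424 and 0.513. Without replicate 2 the xylem list did not pass (adjusted p = 0.0519, limma). Of 12 genes often used as references, 6 rose and 2 fell by their brightest probes (median 0.43; camera adjusted p = 0.0144 in limma, adjusted p = 0.424 with an estimated correlation), with ACT2 at 0.81 ± 0.17. After median centring 11 were higher and 0 lower, with a median 2.64-fold higher, against 1.34-fold after loess. This list did not pass with the mean over probes (median 0.12, adjusted p = 0.160) or with Agilent's processed signals (median 0.31, adjusted p = 0.0643, limma). UBQ10 was at 1.11 ± 0.08 by its brightest probe and 0.51 by the mean over its 11 probes, which ranged from -0.075 to 1.35. The probes of GAPC1 disagreed, with the brightest at 1.31 ± 0.18 and another at -0.28 ± 0.21 (limma adjusted p = 0.0279), and their mean was 0.37.

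The auxin list had 2 genes higher and 11 lower of 24 (median -0.11, against 0.25 after median centring), the gibberellin list 7 and 6 of 19, the ethylene list 9 and 4 of 15, and the expansin and wall list 7 and 5 of 18. The clock list had 3 and 2 of 11, the defence list 3 and 3 of 11, the heat and dehydration list 6 and 2 of 12, the epidermis list 3 and 4 of 11 and the phloem list 1 and 3 of 10. None of these 9 lists passed camera in limma in the paired fit after loess with all 3 arrays. The gibberellin genes GA20OX3 and RGL2 rose by 1.75 ± 0.18 and 1.18 ± 0.24, and the gibberellin list had a median of -0.0073 while its mean and its test pointed upward, and a median of 0.17 after median centring. The defence list had a median of -0.018, against 0.087 after median centring. The expansin and wall list (median 0.55) and the epidermis list (median 0.64) passed camera after median centring (adjusted p = 0.0306 and 0.0227, limma), and the heat and dehydration list passed without replicate 2, without replicate 3 and with no replicate block (adjusted p = 0.00417, 0.0220 and 0.0406, limma). EXPA2 and PDF1.2 rose by 2.42 ± 0.66 and 2.54 ± 0.24, and PR1 fell, at -1.11 ± 0.14. Counts adjusted over the list alone were the same as over all genes for 24 of the 28 lists. They were 12 genes lower for electron transport, 14 lower for carotenoids, 8 higher for expansins and walls and 11 lower for the stomatal lineage.

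Of 22407 genes tested, 12734 (56.8%) passed the threshold, 6147 higher and 6587 lower in SCR:PIF1/pifQ. Most differences were small, with 9887 of the calls under 0.5 on the log2 scale, and 357 genes were at least 2-fold higher and 236 at least 2-fold lower. The 2-fold counts depended on the scaling, with 966 higher and 182 lower after median centring and 475 higher and 438 lower with Agilent's processed signals. Taking the 6 channels as unpaired samples, with no replicate block, gave 6647 genes. Median centring, which moved the median of all genes to 0.16, put 71.0% of calls on the higher side, against 48.3% after loess. Every list was measured in the same 3 pairs of samples, in which the seed list had its median of 2.71.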

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

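The tests of a fixed seed makeup and of position along the chromosomes were chosen only after the result was seen. The others were written down before their result was seen. For the small calls, the orientations and the chromosome segment, the values met the written rule for arguing against the cause. These causes were left open because the verdict also asked for an interval, a share of orientations or a permutation p clear of a limit.

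Red and green signal, which stand for both genotype and dye here, also differed in probes outside the gene table. Of 57 kept probes that the files place on the mitochondrial genome, 43 were higher in SCR:PIF1/pifQ and 0 lower (limma), with medians of 0.72, 0.49 and 0.52 on the 3 arrays. Of 3355 kept probes matched to no gene, 829 were higher and 591 lower, 43 and 22 of them at least 2-fold. Among the 22407 genes tested, 6147 were higher and 6587 lower, 357 and 236 of them at least 2-fold. The unmatched probes were thus not called more often than genes.

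The rise of seed storage and late embryogenesis genes was the largest shift of any list. Probe-linked dye bias was argued against for the 10 of 20 list genes that had other probes. Of these probes 15 of 15 were above 0, with a median log2 ratio of 3.15. Seed material of 1 fixed makeup mixed into the SCR:PIF1/pifQ samples stays open for the list as a whole. At most 1 gene differed between a pair of arrays against the direction of the rest, too few to decide. This test replaced one seen first, in which the red signals of these genes differed between arrays with an SD 4.25, 2.51 and 2.68 times that of genes of like brightness, a result that material of 1 makeup could also give. Slower progress from seed to seedling also stays open, since 8 of 11 genes of reserve mobilisation were higher and 0 lower, ICL and MLS by 2.04 and 1.68, but their median of 0.28 lay between the bounds set for the test, and a direct effect of PIF1 in the endodermis was not tested.

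Of the genes tested, 56.8% passed the threshold, mostly at small fold. A trend with probe GC content as the whole cause was argued against, since 89.9% of the calls remained with the same sign once it was removed. Probe-linked dye bias stays open for part of the small calls: a second probe had the same sign in 80.6% of 3028 genes (95% Wilson interval 79.2 to 82.0), against 59.1% among genes not called, and dye bias shared by both probes of a gene could not be seen this way. The 4 orientations of the arrays' ratios are too few for a share under 0.05; the real one gave 12734 genes and the highest other 0.

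Genes at least 2-fold lower lay close together on chromosome 1. A window of 250 neighbouring genes from AT1G51360 to AT1G54040 held 16 of the 236, ESP and PSAH2 among them, where random orders of the genes had a median of 8. Over all 14 scans looked at (both directions, several windows and 2 fold limits) the permutation p was 0.00300, which argues against chance position, but random orders ignore that neighbours can be duplicated genes. Higher genes also clustered on chromosome 4, from AT4G26980 to AT4G27530, at a permutation p of 0.00400 before that correction. That window includes the seed storage genes SESA1, SESA2, SESA3 and SESA4, all past the threshold as higher. A chromosome segment that differs in sequence between the lines could neither be excluded nor shown: the difference between 2 probes of a gene had a median of 0.12 in the window and 0.13 elsewhere (one-sided permutation p = 0.674). Regulation of these genes by PIF1 was not tested.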

How the results depend on the processing

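The probe GC correction and the added photosystem members were chosen after seeing the data. A fit with no replicate block gave 6647 genes changed, 3052 higher and 3595 lower, and a 2-fold limit gave 593, 357 and 236, below which 76 of 129 named genes fell, PIF1 by its downstream probe (-0.49) among them. Median centring gave 11383 genes higher. Only 52.2% of the calls were shared without the block, all with the same sign, 8 of 129 named genes lost their call and the heat and dehydration list gained one (0.28), and 71.3% with median centring, where 924 genes were called with the opposite sign. Median centring turned the medians of antenna (0.50), photosystem (0.39), electron transport (0.31), Calvin cycle (0.47), chlorophyll (0.096), chloroplast regulator (0.13), starch synthesis (0.0017), auxin (0.25), gibberellin (0.17) and defence (0.087) genes. It also turned LHCB1.4 (0.045), LHCA6 (0.046), LHCB3 (0.20), LHCB4.1 (0.37), PSAK (0.43), GAPB (0.090), EMB3119 (0.25), DXS (0.24) and LTP1 (0.88); the trend of the ratio with brightness, which loess removes, accounts for the difference between these settings by construction. The mean over probes turned PIF1 (0.30), the PIF quartet and SCR list (0.089) and the epidermis list (-0.10). Lists with medians near 0 turned elsewhere, and for these the cause was not tested: gibberellin with background subtracted (0.0065), Agilent's signals (0.051), the deposited table (0.014) and the GC trend removed (0.032); defence without a filter (0.0065) and with a strict one (0.031); epidermis with background subtracted (-0.014) and the GC trend removed (-0.015). With single replicates left out, medians ranged from 0.012 to 0.032 for gibberellin, from -0.043 to -0.0065 for epidermis, from -0.47 to -0.36 for the Calvin cycle (adjusted p 0.0651 without replicate 1) and from -0.25 to -0.17 for chloroplast regulators (adjusted p 0.0509 and 0.0901 without replicates 2 and 3); they ranged from -0.021 to 0.045 for the clock and from -0.049 to 0.022 for defence. Chloroplast regulators also missed the threshold with Agilent's signals (-0.21) and the mean over probes (-0.23), as did the reference genes (0.31 and 0.12). Without replicate 2 the xylem list missed it (-0.19), and the heat and dehydration list passed without replicate 2 (0.34) or 3 (0.31). With an estimated correlation the camera adjusted p was 0.424 for the antenna, photosystem, electron transport, chlorophyll, carotenoid, chloroplast regulator and PIF-bound lists, 0.513 for both starch lists and 0.545 for the Calvin cycle. That way 0 of 28 lists passed (0 also at an unadjusted p under 0.05), and the self-test's moved list was not called either. Electron transport, chloroplast regulators and reference genes had estimated correlations of -0.077, -0.059 and -0.067, below the preset 0.01. A higher correlation among members therefore cannot be why these lists lost their calls. An estimated correlation ties the test to the residual degrees of freedom of 3 arrays, so it could hardly call any list. Its adjusted p values therefore do not argue against a shift. By fry, which compares no list with other genes, gravitropism (0.0145), endodermis (0.0173), ethylene (0.0173), expansins and walls (0.0316) and epidermis (0.0316) passed. With the 7 hyphenated members, 23 of 26 photosystem genes were lower (median -0.55). The 2-fold counts moved to 966 higher and 182 lower with median centring and to 475 and 438 with Agilent's signals. Other counts of all genes changed stayed within 1.5 times, from 9187 genes without replicate 2 to 16028 with median centring. The slide or scan as a block was not run, because all arrays shared 1 slide and 1 scan. Signal over background limits 56 genes in pifQ and 131 in SCR:PIF1/pifQ to a bound.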

Other observations

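Gene families were taken from the array's descriptions after the data were seen, and 14 were tested with camera in limma. Cytosolic ribosomal protein genes were higher in 104 of 173 cases and lower in 13 (median log2 ratio 0.22, adjusted p = 2.38e-09), and proteasome subunit genes were higher in 18 of 23 and lower in 0 (median 0.26, adjusted p = 4.87e-05). Genes described as late embryogenesis abundant, which overlap the seed list, were higher in 18 of 28 and lower in 5 (median 2.09, adjusted p = 4.87e-05). With an estimated correlation the adjusted p was 0.618 for each of these 3. The other 11 families (plastid ribosomal proteins, histones, tubulins, lipid transfer proteins, jacalin lectins, class III peroxidases, cytochromes P450, pentatricopeptide repeat proteins, aquaporins, cyclins, and myrosinases with nitrile specifiers) did not pass camera, with adjusted p from 0.109 to 0.994. A family held only the genes whose description matched, such as 5 cyclins and 8 plastid ribosomal proteins. Of those 8, 5 were lower and 1 higher (median -0.23), so small families were tested with little power.

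The 85 kept probes that the files place on the plastid genome differed between arrays, with medians of 0.13, -0.24 and -0.55, and 8 were higher and 25 lower.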
